A study of Mus musculus with 22 samples.

How the data were processed

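Polyadenylated RNA of mouse kidney cortex was measured in 22 libraries, 1 per animal title. RNA was extracted with TRIzol and libraries were made with the Lexogen QuantSeq 3' FWD kit for Illumina sequencing, per the labels' protocols. The genome build was GRCm38 and the authors used R 3.4.3 and DESeq2 1.18.1, per the submitters' processing notes. The aligner, the counting tool, its strand setting and the annotation release are not given in the sources used here, so genes with near-identical copies or overlapping neighbours carry an uncertainty that cannot be sized. The authors deposited read counts per gene, not normalized, for 16556 genes, and every test below starts from these counts. The smallest total of any gene over the 22 libraries was 66, so genes with few reads do not appear in the table. The authors also deposited a normalized signal, in which each count is divided by 1 DESeq2 size factor per library. The size factors recomputed from the counts equal those implied by that signal, and it was used only for this check. A deposited table of column totals was not used here.

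Genes were identified by the Ensembl identifiers of the table. Of these, 16514 were found in GENCODE release M21, which is on GRCm38 and gave symbols, coordinates and biotypes. Groups were taken from the genotype and age labels and the diet word in the titles, and the number at the end of each title served as the replicate name. No replicate number is shared between groups, so nothing pairs the libraries. Nothing in the labels says whether animals shared a litter, cage or day. Within groups, the 32 library pairs differed by far more than sampling noise (chi-square per degree of freedom 11.6 to 152), so no library was counted more than once. Total counts were 12175804 to 17447367, with 1 library at 53157575; reads without molecular identifiers are not independent molecules, and precision is set by the spread between animals, with a biological coefficient of variation of 20.5%.

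The fit used edgeR 4.0.16 in R 4.3.3 with TMM scaling, filterByExpr over the 6 groups (15064 genes left) and the robust quasi-likelihood F test, all 22 libraries in 1 model with 6 groups and 16 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over the genes tested, with a threshold of 0.05. The 8 contrasts were the genotype difference in each of the 3 settings, its unweighted mean, its variation among the 3 settings (2 degrees of freedom), its change between 15 and 24 months, and the change from 15 to 24 months in each genotype. Levels are TMM-scaled CPM, given as mean ± SD over libraries, and log2 fold changes come from the edgeR fit with their standard errors (SE). For Crat, an exact two-sided permutation test of CPM was added within each setting. With 3 against 3 libraries this exact permutation test cannot go below p = 0.1.

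Before the data were examined, 40 gene lists (pathways, nephron segments and other cell types of the kidney, and stress or handling genes) were fixed and tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 40 lists within a contrast. Each was also tested with the correlation estimated from the data and with fry, which asks whether the genes of a list move one way on balance. No list call in any contrast held with an estimated correlation. Counts of members adjusted over all genes tested stand beside counts adjusted over the list alone. Lists overlap in a few members.

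Genes named in the text follow a rule also fixed beforehand. For each contrast, genes past the threshold with a mean of at least 5 CPM over the samples compared were ranked, and up to 12 with the largest rise and up to 12 with the largest fall were eligible, leaving out gene models without a symbol of their own. Where fewer than 5 genes passed, up to 6 with the smallest p were given as not passing. Up to 4 members of a described list and a set of fixed genes of carnitine and fat metabolism, injury, fibrosis, immunity and the tubule were added. A few genes are not reported here. Exceptions chosen after their values were seen are the genes named for the 2-degree-of-freedom test, Hp in the mean contrast (under 5 CPM), Mzb1 in the overlap of the age effects, Plin4 at 12 months, and the genes given per library in the closing section.

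The test was run on simulated counts drawn from the means and library sizes of these libraries, with 50 genes each changed by 1.5-, 2-, 3- or 4-fold. Each gene was drawn independently of the others with its own fitted spread, the same in all 6 groups. Changed genes were picked among those with a mean of at least 5 CPM. At 12 months (14802 genes in the simulation) it recovered 28%, 74%, 92% and 94% of them, with 6 false calls among 150. At 15 months (14842 genes) the shares were 18%, 72%, 92% and 98%, with 5 false calls among 145, and at 24 months (14822 genes) 40%, 90%, 98% and 100%, with 9 among 173. A simulated list of 20 genes shifted 1.5-fold had a camera p of 5.2e-47 and an unshifted one 0.921. Since the simulated genes do not move together, this cannot test the preset correlation. The shares recovered likewise hold for such genes, not for libraries that differ in many genes at once. Neither these shares nor the false calls speak for a setting whose libraries spread more than the others.

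Alternatives listed beforehand were DESeq2 size factors in place of TMM, no filter on low counts and a stricter one (2 CPM in 3 libraries), removal of mitochondrially encoded genes, DESeq2 1.42.0 (Wald test), limma-voom with sample quality weights, fits with only the groups compared, and each library left out in turn. For the variation among the 3 settings, DESeq2 was run with its likelihood ratio test in place of the Wald test. Added after the data were seen were a correction for GC content (over the last 300 nt of the transcript, with a lowess span of 0.3; 99.8% of tested genes had a value), the deepest library thinned to the median depth, and 2 pairs of libraries left out together. Adjusted p-values that DESeq2 left missing stayed missing. Other splits of the libraries were refitted, all of them where there were at most 100 and 100 drawn with a fixed seed otherwise. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.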

Results

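Messenger RNA was measured in the kidney cortex of 22 male C57BL/6J mice by 3' tag sequencing, in which each transcript is read near its 3' end. The study removed carnitine acetyltransferase, the mitochondrial enzyme encoded by Crat that moves acetyl groups between coenzyme A and carnitine, from proximal tubular cells with a Cre recombinase driven by the Ggt promoter. Animals with the deletion are called Pt-CrAT and their floxed counterparts fl/fl. They were sampled in 3 settings: 12 months of age with "LFD" in the sample title (3 fl/fl and 3 Pt-CrAT), 15 months with chow in the title (3 and 3), and 24 months with chow in the title (5 and 5). The meaning of LFD is not spelled out in the labels. Since it changes together with age, the 12-month animals were not set against the older ones. The labels name no batch, cohort or dissection day, so the ages may also differ in these. Libraries are named by their titles, in which CrAT stands for Pt-CrAT and Wt for fl/fl. Total counts ran from 12175804 to 17447367 per library, apart from CrAT12MLFD345 at 12 months with 53157575. The table held 16556 genes, of which 15064 were tested. Transcripts of the mitochondrial chromosome took between 4.67% and 6.58% of the counts of each library.

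The targeted gene was examined first. Crat (ENSMUSG00000026853; GRCm38 chromosome 2, 30400471 to 30415813, minus strand) is covered here by tags near its 3' end; the sources used here do not say which part was deleted. At 24 months it stood at 74.7 ± 24.4 CPM in fl/fl and 36.2 ± 4.41 CPM in Pt-CrAT libraries (SD, n = 5 each; log2 fold change -1.04, SE 0.21). All 5 Pt-CrAT libraries (28.4 to 38.9 CPM) lay below all 5 fl/fl libraries (43.5 to 112 CPM). The exact two-sided permutation test of CPM gave p = 0.00794, the smallest it can give with 5 against 5. Over all genes the edgeR quasi-likelihood test left Crat at an adjusted p of 0.177 there. At 12 months the levels were 78.9 ± 22.5 CPM in fl/fl and 62.5 ± 19.4 CPM in Pt-CrAT (SD, n = 3 each; log2 fold change -0.33, SE 0.27, adjusted p = 0.41; exact permutation p = 0.4). At 15 months Crat went against the labels: the libraries labelled Pt-CrAT held 69.1 ± 5.27 CPM and those labelled fl/fl 45.3 ± 13.3 CPM (SD, n = 3 each; log2 fold change 0.61, SE 0.27, adjusted p = 0.581). All 3 of the former lay above all 3 of the latter. The exact permutation p was 0.1, the smallest possible with 3 against 3. For this reason the animals at 15 months are called by their labels below. The genotype difference in Crat varied among the 3 settings (adjusted p = 0.0319). That test was unstable over all genes: the number passing, 764, ranged from 2 to 2195 with 1 library left out.

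**Figure D1:**
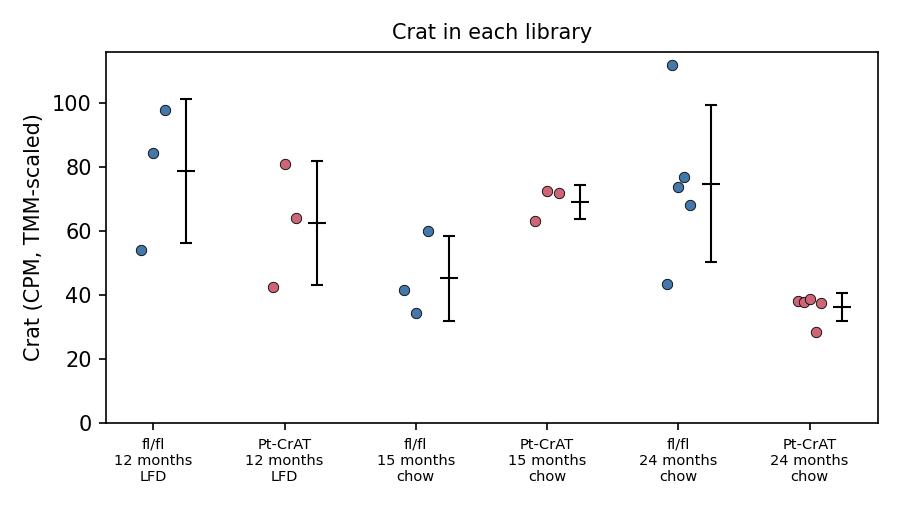
Crat in each of the 22 libraries, in TMM-scaled CPM (vertical axis), by genotype and setting; points are libraries, and the bars give the mean and SD of the group. Pt-CrAT libraries at 24 months lie between 28.4 and 38.9 CPM, below the fl/fl libraries, while at 15 months those labelled Pt-CrAT lie above those labelled fl/fl.

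At 12 months, single complement and acute-phase genes and 6 of 8 adipocyte genes rose in Pt-CrAT. C3, the central complement component (ENSMUSG00000024164; chromosome 17, 57203970 to 57228136), rose from 10.2 ± 2.46 to 31.4 ± 3.98 CPM (SD, n = 3 each; log2 fold change 1.62, SE 0.25, adjusted p = 0.00278). It was higher in 3 of 3 Pt-CrAT libraries than in any fl/fl library. Of 13 complement and acute-phase genes tested, 4 rose and none fell: C3, the haemoglobin scavenger Hp (log2 fold change 3.18), Lrg1 (0.83) and C4b (0.74), whose tags the authors' counting could split with its near-identical copy C4a. When adjusted over the list alone, 4 rose and 2 fell. The list as a whole did not pass (camera adjusted p = 0.407). Among 8 adipocyte genes, 6 rose, with a median log2 fold change of 3.03. They include the adipokines Adipoq (5.01, SE 1.08, adjusted p = 0.00927), Cfd (4.18) and Retn (4.62) and the carbonic anhydrase Car3 (1.60, SE 0.53; 167 ± 93.8 to 506 ± 188 CPM), which the cortex of both genotypes also expresses. The same 6 passed adjusted over the list alone. This was the only one of 40 gene lists that camera called at 12 months (camera adjusted p = 0.00939; adjusted p = 0.99 with an estimated correlation; fry adjusted p = 0.0705). Camera did not call it without CrAT12MLFD345 (camera adjusted p = 0.166). The largest rise of all named genes was in Myoc, which encodes myocilin (6.11, SE 0.95, adjusted p = 0.00363; from 0.17 ± 0.0913 to 11.9 ± 4.24 CPM). In CrAT12MLFD328, CrAT12MLFD337 and CrAT12MLFD345, Hp stood at 5.48, 13.1 and 17.8 CPM, in the order of Adipoq (5.75, 14.1 and 28 CPM). C3 stood at 26.8, 34.3 and 33.1 CPM there. Whether the rise of Hp is separate from that of the adipocyte genes was not tested. Of the genes named in this paragraph, C3, Hp, Adipoq, Retn and Myoc kept their call without CrAT12MLFD328 or CrAT12MLFD337, and C3, Hp, C4b and Myoc without Wt12MLFD326. Car3 also lost its call without CrAT12MLFD345 (adjusted p = 0.0933) and Wt12MLFD327 (0.0663).

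**Figure D2:**
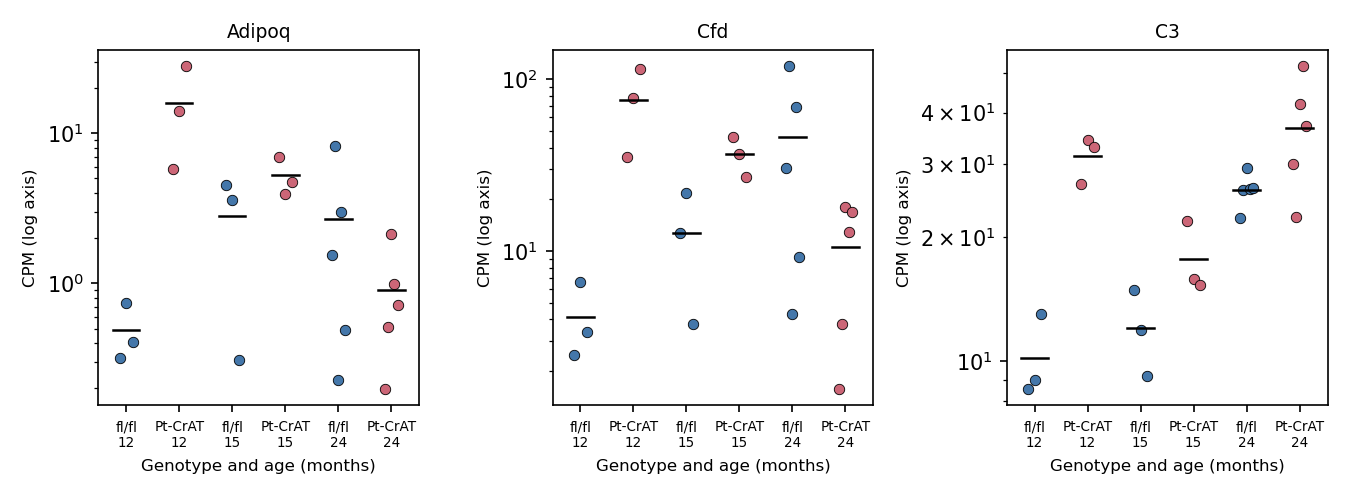
Adipoq, Cfd and C3 in each library (CPM on a log axis) by genotype and age in months; points are libraries and lines are group means. Adipoq averages 16 CPM in Pt-CrAT and 0.487 CPM in fl/fl libraries at 12 months, and spreads from 0.226 to 8.24 CPM among the fl/fl libraries at 24 months.

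Genes of mitochondrial metabolism went both ways at 12 months. Of 71 nuclear-encoded genes of oxidative phosphorylation, 15 rose, such as the complex I genes Ndufb7 (log2 fold change 0.86, SE 0.16) and Ndufs8 (0.80, SE 0.17), and 6 fell, such as Ndufc2 (-0.68) and Ndufv2 (-0.51). Adjusted over the list alone, 17 rose and 8 fell. Of 28 genes of the citric acid cycle and pyruvate oxidation, 1 rose and 7 fell (2 and 10 adjusted over the list alone), including the isocitrate dehydrogenase subunit Idh3a (-0.81) and dihydrolipoamide dehydrogenase Dld (-0.74). Of 19 genes of branched-chain amino acid catabolism, 2 rose and 6 fell (2 and 8 adjusted over the list alone), with Hibch at -1.13 and Pccb at -0.60 against Bckdha at 0.77. Of 21 genes of mitochondrial fatty acid oxidation, 3 rose, namely the short-chain dehydrogenase Acads (1.10), the thiolase Acaa2 (0.93) and Etfb (0.87), and 6 fell, among them Etfa (-1.72) and the medium-chain dehydrogenase Acadm (-0.70). Without Wt12MLFD326 these 2 stood at -0.68 (adjusted p = 0.184) and -0.31 (adjusted p = 0.367), and of the genes named here Ndufb7, Ndufs8, Ndufv2, Acads and Acaa2 kept their call. Without CrAT12MLFD337, Ndufb7, Ndufs8, Acads, Acaa2 and Etfb kept theirs, and without CrAT12MLFD328 none did. Adjusted over the list alone the counts were again 3 and 6. None of these lists passed as a whole (camera adjusted p = 0.423, 0.261, 0.134 and 0.556 in this order). The carnitine enzymes Cpt1a (-0.19, adjusted p = 0.482) and Crot (-0.09, adjusted p = 0.818) did not pass.

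Among 20 markers of the first proximal tubule segments, S1 and S2, none rose and 4 fell (5 adjusted over the list alone; camera adjusted p = 0.423). These were the amino acid transporter Slc7a8 (log2 fold change -1.88, SE 0.44), the endocytic receptor megalin, Lrp2 (-1.12, SE 0.28), the creatine synthesis enzyme Gatm (-1.37) and the urate transporter Slc22a12 (-1.15). Without Wt12MLFD326 none of the 4 passed (-1.20, -0.91, -0.98 and -0.73 in this order; adjusted p = 0.11, 0.0994, 0.125 and 0.282). Ggt1, whose promoter family drives the Cre, rose (0.98, SE 0.22, adjusted p = 0.00978), and the phosphate transporter Slc34a1 did not pass (0.29, adjusted p = 0.287). Of 31 genes of lipid storage and uptake, 5 rose and 1 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.441). The lipid droplet genes Cidec (3.77), Plin1 (3.42) and Plin4 (2.28) among those that rose are abundant in adipocytes, whose markers were higher in the same libraries (median 3.03). The fatty acid synthase Fasn rose by 0.82 (SE 0.25). Of 14 senescence genes, 1 rose (Igfbp6, 2.98) and 4 fell, among them the protease Mmp3 (-3.72), Igfbp3 (-1.55) and Igfbp4 (-0.65). Mmp3 lay near the floor, at 0.479 ± 0.185 CPM in fl/fl and 0.0343 ± 0.0427 CPM in Pt-CrAT, so its fold rests on few reads. The list did not pass in camera (camera adjusted p = 0.123; 1 rose and 6 fell adjusted over the list alone) and was the only list that fry called at 12 months (fry adjusted p = 0.00967). The largest falls included the redox regulator Txnip (-2.57, SE 0.82, adjusted p = 0.0413), the tight junction protein Tjp1 (-2.02, SE 0.44), Susd6 (-2.42), the selenoprotein Selenof (-2.28) and the proteasome subunit Psma5 (-2.07). Txnip stood at 607 CPM in Wt12MLFD326, against 87.5 and 94.2 CPM in the other fl/fl libraries, and Tjp1 at 51.6 CPM in that library against 10.4 and 13.8 CPM. Without it Txnip stood at -1.03 (adjusted p = 0.473), Tjp1 at -0.95 (0.0775), Susd6 at -1.28 (0.276), Selenof at -1.14 (0.291) and Psma5 at -1.01 (0.258). Several of the genes that fell also varied within fl/fl at 24 months, where genotype plays no part. In Wt24Mchow145 and Wt24Mchow154, Txnip stood at 162 and 30.9 CPM, Selenof at 26.8 and 4.12, and Tjp1 at 18.8 and 10.3. Slc7a8 stood there at 141 and 37.1 CPM and Lrp2 at 1510 and 618. The cause of this spread was not tested. Further large rises were in Cpxm2 (3.06), Capn15 (1.78), the imprinted long noncoding RNA Meg3 (1.61), Pi16 (1.45) and the transcription factor Nfatc4 (1.44). Of the genes named in this paragraph, Cpxm2, Capn15, Meg3 and Mmp3 kept their call without Wt12MLFD326, while Ggt1 (adjusted p = 0.0545), Cidec (0.0539), Plin1 (0.111), Plin4 (0.112), Fasn (0.189), Igfbp6 (0.0732), Igfbp3 (0.181), Igfbp4 (0.0852), Pi16 (0.0944) and Nfatc4 (0.114) did not. Cpxm2, Meg3 and Cidec alone kept theirs without CrAT12MLFD328, and these 3 with Capn15, Ggt1, Igfbp6 and Mmp3 without CrAT12MLFD337. Plin4 lost its call with each of the 6 libraries left out in turn (0.0903 to 0.158), Plin1 also without CrAT12MLFD345 (0.0632) and Fasn also without Wt12MLFD368 (0.0507).

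In all, 2464 of 15064 genes passed at 12 months, 1267 higher and 1197 lower in Pt-CrAT. This number rested on few libraries: it was 53 without CrAT12MLFD328, 391 without CrAT12MLFD337, and 408 without Wt12MLFD326. It was 19 without CrAT12MLFD328 and Wt12MLFD326 together. The last is an alternative added after the data were seen. Of the genes named or eligible to be named for 12 months, 30 were called lower and 28 higher, of which 2 and 12 kept their call without Wt12MLFD326, 0 and 8 without CrAT12MLFD328, and 1 and 16 without CrAT12MLFD337. With only the 6 libraries of this setting in the fit, 1 gene passed. The fit of all 22 libraries takes 1 spread per gene over the 6 groups. The fl/fl pairs with Wt12MLFD326 differed more (chi-square per degree of freedom 104 and 152) than the other fl/fl pair of this setting (29.6). The 2464 calls therefore rest on a shared spread that may be too small for this setting. Whether this accounts for the drop to 1 was not tested.

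**Figure D3:**
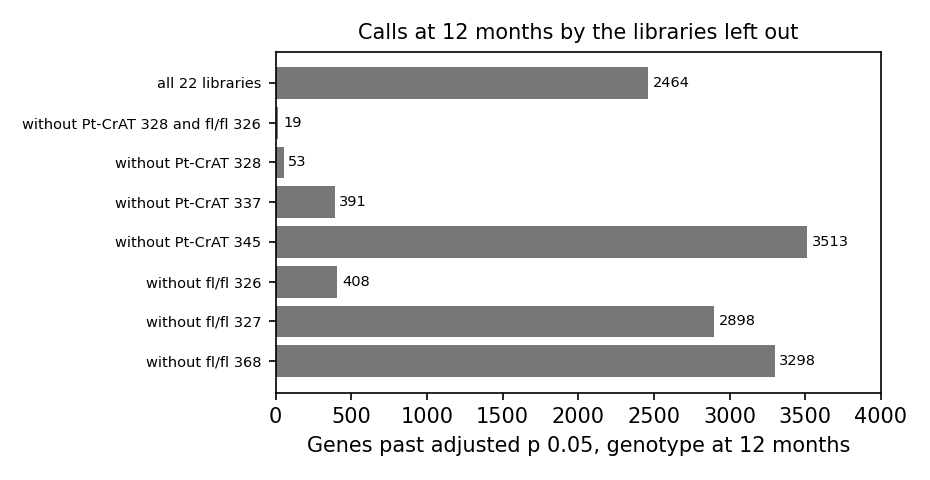
Number of genes past an adjusted p of 0.05 between the genotypes at 12 months (horizontal axis) with all 22 libraries in the fit and with each named library left out. The number is 2464 with all libraries and ranges from 53 to 3513 with 1 library left out; it is 19 with CrAT12MLFD328 and Wt12MLFD326 left out together.

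At 15 months edgeR called no gene between the labelled genotypes, while camera called 3 gene lists. Of 27 macrophage and myeloid genes, 22 had higher values in the libraries labelled Pt-CrAT (median log2 fold change 0.25; camera adjusted p = 0.00751, adjusted p = 0.705 with an estimated correlation). The calgranulin genes S100a8 and S100a9 stood at 1.40 (SE 0.69) and 1.47 (SE 0.64), and the phagocyte oxidase gene Cybb at 0.78 (SE 0.31), each at an adjusted p of 0.581. Of 8 genes of the thin limb and medulla, 7 had lower values (median -0.86; camera adjusted p = 0.00751, adjusted p = 0.635 with an estimated correlation), such as the urothelial plaque gene Upk1b at -2.33 (SE 0.83) and the chaperone Cryab at -0.79 (SE 0.34). Of 6 erythrocyte genes, 5 had lower values (median -0.58; camera adjusted p = 0.00751, adjusted p = 0.705 with an estimated correlation), with the haemoglobin genes Hba-a2 at -0.88 (SE 0.27) and Hba-a1, a near-identical copy, at -0.80 (SE 0.26). Adjusted over the list alone, 2 erythrocyte genes passed, and no gene of the other lists named here did. The macrophage list was not called without CrAT15Mchow183 (camera adjusted p = 0.185) or Wt15Mchow227 (0.0547), nor the erythrocyte list without CrAT15Mchow183 (0.0637).

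The edgeR test called 0 genes at 15 months, with 1249 genes at an unadjusted p under 0.05 where 753 would be expected by chance, and a smallest adjusted p of 0.581. DESeq2 called 0 (1425 at an unadjusted p under 0.05), and limma-voom called 1. The genes with the smallest p, none passing, were Cavin3 (-1.15, SE 0.25), Igfbp2 (-2.66, SE 0.65), the basal keratin Krt15 (-3.00, SE 0.73), the GABA receptor subunit Gabre (2.36, SE 0.59), the tubulin Tubb2a (-1.09, SE 0.28) and Dpy19l1 (-0.81, SE 0.21), most of them at a few CPM. The directions here are those of the labels, against which Crat ran in these 6 libraries.

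At 24 months edgeR again called no gene, while camera called lists of energy metabolism genes with lower values in Pt-CrAT. Of 71 nuclear-encoded oxidative phosphorylation genes, 57 had lower values (median log2 fold change -0.18; camera adjusted p = 5.2e-08, adjusted p = 0.364 with an estimated correlation), such as the complex III subunits Uqcrc1 (-0.37, SE 0.11) and Uqcrq (-0.31, SE 0.11). Of 8 mitochondrially encoded transcripts, 7 had lower values (median -0.25; camera adjusted p = 0.005, adjusted p = 0.364 with an estimated correlation), with mt-Nd5 at -0.45 (SE 0.14). Genes of mitochondrial fatty acid oxidation (17 of 21 lower, median -0.15) and of lipid storage and uptake (22 of 31 lower, median -0.09) each had a camera adjusted p of 0.00885, and an adjusted p of 0.364 with an estimated correlation. Examples are Acads (-0.63, SE 0.17), the lipoprotein lipase gene Lpl (-0.62, SE 0.18) and Hilpda (-0.43, SE 0.13). Genes of acetyl-CoA and acyl-CoA handling (16 of 21 lower, median -0.13) and markers of proximal tubule S1 and S2 (15 of 20 lower, median -0.18) each had a camera adjusted p of 0.0167, with adjusted p = 0.38 and 0.418 with an estimated correlation. Cholesterol synthesis genes (19 of 24 lower, median -0.10; camera adjusted p = 0.0264) and markers of proximal tubule S3 (10 of 10 lower, median -0.17; camera adjusted p = 0.0443) also shifted, with adjusted p = 0.418 and 0.427 with an estimated correlation.

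Androgen-responsive and sex-biased kidney genes were lower as a group at 24 months (12 of 15, median -0.43; camera adjusted p = 3.46e-04, adjusted p = 0.364 with an estimated correlation), for example the polyamine enzyme Odc1 (-0.91, SE 0.36) and Cyp2j13 (-0.92, SE 0.38). Tubular injury genes had higher values (19 of 26, median 0.15; camera adjusted p = 0.0264, adjusted p = 0.38 with an estimated correlation), with osteopontin, Spp1, at 0.55 (SE 0.17) and Cd44 at 0.79 (SE 0.25). So did immediate early and handling-related genes (10 of 13, median 0.33; camera adjusted p = 0.0491, adjusted p = 0.418 with an estimated correlation). Adipocyte genes (7 of 8 lower, median -1.39; camera adjusted p = 0.01, adjusted p = 0.418 with an estimated correlation) and erythrocyte genes (6 of 6 lower, median -0.42; camera adjusted p = 0.00154, adjusted p = 0.38 with an estimated correlation) were lower, so markers of other cells moved alongside these groups. CrAT24Mchow123 and CrAT24Mchow136 stood apart in this setting, with 4570 and 2850 CPM of the androgen-dependent transcript Kap where the other libraries of this age held 18900 CPM or more. Without these 2 libraries together, chosen after the data were seen, 8 lists were called, of which 4 were among the 13. The oxidative phosphorylation, erythrocyte, lipid storage and adipocyte lists still passed (camera adjusted p = 8.06e-05, 0.00166, 0.0355 and 0.005). The androgen-responsive (0.0858), mitochondrially encoded (0.0815), fatty acid oxidation (0.0936), acetyl-CoA (0.359), S1 and S2 (0.611), injury (0.44), cholesterol (0.308) and immediate early (0.274) lists did not. The S3 list changed sign (0.872). The 4 lists called only without the pair had higher values in Pt-CrAT: T and NK cells (0.00224, against 0.0659 with all libraries), fibrosis and matrix (0.005 against 0.121), macrophages (0.0116 against 0.237) and inflammatory signalling (0.0297 against 0.121). An estimated correlation was not run without the pair.

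With 1 library left out at 24 months, the oxidative phosphorylation, mitochondrially encoded, androgen-responsive and erythrocyte lists stayed called each time. Without CrAT24Mchow123 the call was lost (camera adjusted p) by fatty acid oxidation (0.0564), lipid storage (0.0613), acetyl-CoA handling (0.133), S1 and S2 (0.1), S3 (0.273), injury (0.0587) and immediate early genes (0.0587). Without CrAT24Mchow136 it was lost by cholesterol synthesis (0.207), S1 and S2 (0.0534), S3 (0.137), injury (0.103) and immediate early genes (0.103). Without Wt24Mchow145 it was lost by acetyl-CoA handling (0.123), cholesterol synthesis (0.057), S1 and S2 (0.0544), S3 (0.241), injury (0.0544) and immediate early genes (0.0656). The adipocyte (0.0596), injury (0.072) and immediate early (0.0603) lists lost it without Wt24Mchow154, the immediate early list without Wt24Mchow164 (0.196), and the cholesterol (0.0847) and immediate early (0.11) lists without Wt24Mchow165. Without Wt24Mchow168 the cholesterol (0.0899), S1 and S2 (0.109) and S3 (0.0782) lists lost it.

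The edgeR test called 0 genes at 24 months, with 1409 at an unadjusted p under 0.05 and 753 expected by chance. DESeq2 called 6, with 15728 of its 16556 adjusted p-values missing, and limma-voom 3. Nearest to the threshold were the shear-responsive transcription factor Klf2 (ENSMUSG00000055148; chromosome 8, 72319033 to 72321656; 21.9 ± 1.9 CPM in fl/fl and 36.8 ± 7.57 CPM in Pt-CrAT, SD, n = 5 each; log2 fold change 0.75, SE 0.13, adjusted p = 0.0771), higher in 5 of 5 Pt-CrAT libraries than in any fl/fl library, and the protease Adamts15 (-0.91, SE 0.16, adjusted p = 0.0771), lower in 5 of 5. Stc1 (1.27, SE 0.24, adjusted p = 0.0878), the chromatin regulator Brpf1 (0.62, SE 0.12, adjusted p = 0.103) and the clock gene Per1 (1.21, SE 0.24, adjusted p = 0.129) followed. Among genes fixed beforehand, Crot (-0.57, SE 0.17), Ggt1 (-0.53, SE 0.17) and Fasn (-0.59, SE 0.20) did not pass.

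Averaged over the 3 settings, 4 genes rose in Pt-CrAT and none fell. They were C3 (log2 fold change 0.89, SE 0.13, adjusted p = 0.00789), Hp (1.49, SE 0.27, adjusted p = 0.0443), the RNA-binding protein gene Prrc2c (0.53, SE 0.09, adjusted p = 0.0342) and the ciliary gene Cep290 (0.51, SE 0.09, adjusted p = 0.0342). C3 stood at 1.62, 0.56 and 0.50 in the settings at 12, 15 and 24 months. Cep290 stood at 1.22, 0.30 and 0.01. Mean levels of Hp in fl/fl and Pt-CrAT were 1.34 and 12.1 CPM at 12 months, 1.87 and 5.1 CPM at 15, and 3.45 and 3.06 CPM at 24. Those of Prrc2c were 66.1 and 156, 141 and 178, and 203 and 207 CPM. For Hp, Prrc2c and Cep290 the genotype difference varied among the settings (edgeR test on 2 degrees of freedom, adjusted p = 0.02 each). Their mean therefore does not stand for a rise in every setting. Complement and acute-phase genes were higher as a list (2 of 13 rose, 4 adjusted over the list alone; camera adjusted p = 0.0312, adjusted p = 0.553 with an estimated correlation), as were macrophage genes (23 of 27 with higher values; camera adjusted p = 0.0275, adjusted p = 0.629 with an estimated correlation) and adipocyte genes (7 of 8; camera adjusted p = 0.0275, adjusted p = 0.617 with an estimated correlation). Genes of the citric acid cycle and pyruvate oxidation (19 of 28 with lower values, 3 falls adjusted over the list alone) and markers of proximal tubule S3 (9 of 10, 5 falls adjusted over the list alone) were lower, each at a camera adjusted p of 0.0124. Branched-chain amino acid catabolism (15 of 19; camera adjusted p = 0.0143) and erythrocyte genes (5 of 6, 4 falls adjusted over the list alone; 0.017) were lower too. All 4 of these lists had an adjusted p of 0.617 with an estimated correlation. The adipocyte list, higher in the mean, was called lower at 24 months (median -1.39, camera adjusted p = 0.01).

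Of the 7 lists called for the mean, the macrophage list lost its call without CrAT12MLFD328 and Wt12MLFD326 together (camera adjusted p = 0.258), the only one to do so. It also lost it without CrAT15Mchow183 (0.0792), Wt15Mchow227 (0.0733), Wt24Mchow168 (0.0682) or Wt12MLFD326 (0.113). The adipocyte list lost its call without CrAT15Mchow183 (0.0792), CrAT24Mchow136 (0.0818) or CrAT12MLFD345 (0.147). The complement list lost it without CrAT15Mchow183 (0.0511), CrAT24Mchow136 (0.0759), CrAT12MLFD345 (0.0997) or Wt12MLFD327 (0.137). The erythrocyte list lost it without CrAT12MLFD345 (0.0587), Wt12MLFD327 (0.0671) or Wt12MLFD368 (0.126).

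The count of 4 was unstable, at 178 with DESeq2, 1881 with limma-voom, 262 without Wt24Mchow154 at 24 months, 170 without CrAT12MLFD345 and 49 without Wt12MLFD327 at 12 months, and 1 or 2 without any one of 15 further libraries. The mean includes the 15-month libraries, in which Crat ran against the labels.

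Whether the genotype difference itself varied among the settings was tested on 2 degrees of freedom, and 764 genes passed. Since this test has no single direction, some of the genes with the smallest p are named, a choice made after the data were seen. Smim1 (adjusted p = 0.0189) and further genes at 0.02 are listed in the closing sections. Most of those named here were higher in Pt-CrAT at 12 months and lower at 24 months. The mitochondrial import factor Timm13 (adjusted p = 0.0143) had log2 fold changes of 1.24, 0.12 and -0.37 at 12, 15 and 24 months, and Uap1l1 (adjusted p = 0.0143) had 0.87, 0.46 and -0.61. Acads (1.10, 0.26 and -0.63), the peroxisomal thioesterase gene Acot8 (0.79, -0.25 and -0.35), Ndufb7 (0.86, 0.03 and -0.31) and Ggt1 (0.98, 0.32 and -0.53) each had an adjusted p of 0.02. Klf2 went the other way, with -0.44, -0.33 and 0.75 (adjusted p = 0.02). The number fell to 2 without CrAT12MLFD337, 6 without CrAT12MLFD328, 2 without CrAT12MLFD328 and Wt12MLFD326 together, and 30 without CrAT24Mchow123 and CrAT24Mchow136 together, and it rose to 2195 without CrAT12MLFD345 at 12 months.

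Between the chow settings alone, the genotype difference changed from 15 to 24 months in 0 genes by edgeR (2255 at an unadjusted p under 0.05), 15 by DESeq2 and, rounded, 1.5e2 by limma-voom. The smallest adjusted p of any gene was 0.112. Leaving out gene models without a symbol of their own, those with the smallest p included Klf2 (1.08, SE 0.21, adjusted p = 0.201) and Uap1l1 (-1.07, SE 0.23). They also included Crat (-1.66, SE 0.35), the adrenergic receptor gene Adra2a (1.88, SE 0.42) and Slc45a3 (1.95, SE 0.44). Uap1l1, Crat, Adra2a and Slc45a3 each had an adjusted p of 0.266. The lists were also tested on this contrast, an addition made after seeing the data. Camera called 6 of them. The genotype difference (Pt-CrAT minus fl/fl) was lower at 24 than at 15 months in genes of the carnitine system (9 of 10, median -0.31; camera adjusted p = 0.0428), mitochondrial fatty acid oxidation (17 of 21, median -0.36; 0.0343), lipid storage and uptake (20 of 31, median -0.24; 0.0343) and adipocytes (7 of 8, median -1.93; 0.0343). It was higher in genes of the thin limb and medulla (7 of 8, median 1.11; 0.0343) and the thick ascending limb (10 of 10, median 0.35; 0.0428). With an estimated correlation the adjusted p was 0.77 for adipocytes and 0.648 for the others, and fry called none. Camera called 0 lists without CrAT24Mchow123 and CrAT24Mchow136 together, and also 0 without CrAT24Mchow123, Wt15Mchow225 or Wt24Mchow145 alone, 2 without Wt24Mchow164, and up to 9 (without CrAT24Mchow124) with another library left out. Markers of other cells thus moved alongside the metabolic lists. The direction of this contrast rests in part on the 15-month labels.

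From 15 to 24 months in fl/fl, some macrophage genes rose and some clock genes fell. Of 27 macrophage and myeloid genes, 7 rose and none fell (10 rose adjusted over the list alone; median log2 fold change 0.77; camera adjusted p = 2.06e-11, adjusted p = 0.203 with an estimated correlation), among them the fractalkine receptor Cx3cr1 (1.30, SE 0.26; 22.7 ± 4.25 to 55.9 ± 13.9 CPM, SD, n = 3 and 5), S100a8 (2.90, SE 0.66) and Fcer1g (1.21, SE 0.28). Of 20 interferon response genes, 2 rose, Ifit3 (0.82) and Ifi44 (0.79), and 8 adjusted over the list alone (camera adjusted p = 3.88e-05, adjusted p = 0.203 with an estimated correlation). Of 36 fibrosis and matrix genes, 1 rose, the collagen crosslinking enzyme Lox (1.56), and 9 adjusted over the list alone (camera adjusted p = 7.04e-05, adjusted p = 0.276 with an estimated correlation). Cdkn1a, which encodes the cell cycle inhibitor p21 (ENSMUSG00000023067; chromosome 17, 29090976 to 29100727), rose from 3.73 ± 0.337 to 10.8 ± 2.39 CPM (1.53, SE 0.27, adjusted p = 0.0143). C3 rose by 1.11 (SE 0.22). Other large rises were in Lrrc17 (2.01), the aldehyde dehydrogenases Aldh1a1 (1.75) and Aldh1a7 (1.24), which are close paralogs, the transcription factor Foxs1 (1.60) and the fatty acid hydroxylase Cyp4a10 (1.33).

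Of 17 clock genes, 4 fell, namely Per2 (-2.23, SE 0.53), Dbp (-1.52, SE 0.35), Bhlhe41 (-1.37, SE 0.35) and Per1 (-1.25, SE 0.27). Adjusted over the list alone 3 rose and 10 fell (camera adjusted p = 0.00119, adjusted p = 0.203 with an estimated correlation). The time of day of sampling is not given in the labels. Of 20 markers of proximal tubule S1 and S2, 1 fell, the glucose transporter Slc5a2 (-0.80, SE 0.18), and 8 adjusted over the list alone (camera adjusted p = 1.22e-06, adjusted p = 0.203 with an estimated correlation). Of 10 markers of the distal convoluted and connecting tubule, 2 fell, calbindin, Calb1 (-1.06, SE 0.20), and the kallikrein Klk1 (-0.85, SE 0.20), and 4 adjusted over the list alone (camera adjusted p = 1.07e-04, adjusted p = 0.203 with an estimated correlation). The N-acetyltransferase paralogs Nat8f5 (-2.10) and Nat8f6 (-1.57), the coagulation factor F5 (-1.39), Ltc4s (-1.29), the mitochondrial adenylate kinase Ak4 (-1.27) and the anion exchanger Slc26a4 (-1.03) also fell. Of 21 genes of acetyl-CoA handling, 2 fell, the mitochondrial acetyl-CoA synthetase Acss1 (-0.82) and the deacetylase Sirt3 (-0.43), and 3 adjusted over the list alone (camera adjusted p = 0.0122, adjusted p = 0.276 with an estimated correlation).

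In all, 196 genes passed in fl/fl, 72 of them lower and the others higher at 24 months, and 17 of the 40 lists were called. The number was 3, 4 and 53 without Wt15Mchow227, Wt15Mchow205 and Wt15Mchow225 at 15 months, and 41, 63, 68 and 756 without Wt24Mchow165, Wt24Mchow164, Wt24Mchow154 and Wt24Mchow145 at 24 months. DESeq2 called 731 and limma-voom 2024. The 15-month animals are those labelled fl/fl.

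From 15 to 24 months in animals labelled Pt-CrAT, 11 of 20 markers of proximal tubule S1 and S2 fell, and some tubular injury, matrix and immune genes rose. None of these 20 markers rose, and the same 11 fell adjusted over the list alone (median log2 fold change -0.62; camera adjusted p = 5.51e-10, adjusted p = 0.0536 with an estimated correlation), among them Slc5a2 (-1.24, SE 0.18; 284 ± 13.6 to 120 ± 30.7 CPM, SD, n = 3 and 5), the neutral amino acid transporter Slc6a19 (-0.88, SE 0.14) and the phosphate transporters Slc34a3 (-1.47, SE 0.24) and Slc34a1 (-0.79, SE 0.17). Of 26 tubular injury genes, 9 rose and 2 fell (14 and 3 adjusted over the list alone; camera adjusted p = 3.92e-05, adjusted p = 0.0666 with an estimated correlation), with the lipocalin NGAL, Lcn2, at 3.99 (SE 0.64, adjusted p = 0.00128; 0.222 ± 0.115 to 3.69 ± 2.61 CPM), KIM-1, Havcr1, at 2.47 (SE 0.64) and Vcam1 at 0.79 (SE 0.18). Of 36 fibrosis and matrix genes, 8 rose and none fell (14 rose adjusted over the list alone; camera adjusted p = 1.78e-06, adjusted p = 0.157 with an estimated correlation), including smooth muscle actin, Acta2 (1.04), the intermediate filament Vim (0.91) and the protease Mmp14 (0.86). Of 27 macrophage and myeloid genes, 7 rose (12 adjusted over the list alone; camera adjusted p = 2.75e-05, adjusted p = 0.244 with an estimated correlation), including Adgre1 (1.58) and Lyz2 (1.19). Of 16 genes of B and plasma cells, 7 rose (10 adjusted over the list alone; camera adjusted p = 1.65e-04, adjusted p = 0.209 with an estimated correlation), led by the immunoglobulin genes Ighg2c (5.17, SE 1.03) and Ighg2b (3.80, SE 0.77), which share sequence. In fl/fl, mean levels also rose for Lcn2 (0.434 to 1.89 CPM), Havcr1 (1.16 to 4.63), Vcam1 (21.2 to 32), Ighg2c (1.56 to 13.4) and Ighg2b (2.22 to 12.1). Camera called the tubular injury list there too, but not without Wt15Mchow205 (camera adjusted p = 0.0597), Wt24Mchow145 (0.0782) or Wt24Mchow168 (0.0629). These rises are thus not shown to be particular to Pt-CrAT.

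Some genes of energy metabolism fell in the same comparison. Of 71 nuclear-encoded oxidative phosphorylation genes, 11 fell and none rose (16 fell adjusted over the list alone; camera adjusted p = 1.76e-06, adjusted p = 0.209 with an estimated correlation). Of 21 mitochondrial fatty acid oxidation genes, 6 fell and none rose (1 rose and 8 fell adjusted over the list alone; camera adjusted p = 1.97e-04, adjusted p = 0.0764 with an estimated correlation). The carnitine palmitoyltransferase Cpt1a (-0.72, SE 0.16), Angptl4 (-0.96, SE 0.23) and Crat itself (-0.93, SE 0.24, adjusted p = 0.0165) fell. The PPAR targets Cyp4a14 (4.42) and Acot1 (0.92, SE 0.20) rose. Of 31 lipid storage genes, 6 fell and none rose (1 rose and 8 fell adjusted over the list alone; camera adjusted p = 3.52e-04, adjusted p = 0.0666 with an estimated correlation). The urothelial genes Upk3a (3.74, SE 0.68) and Psca (3.74, SE 0.73), the cornified envelope gene Sprr1a (3.52, SE 0.55) and the near-identical gasdermin copies Gsdmc2 (3.97) and Gsdmc3 (3.81) were among the largest rises. C4a (-2.41), the anion transporter Slc22a7 (-2.25), F5 (-2.23), Ces1g (-2.21) and the organic solute transporter Slc51a (-1.71) were among the largest falls. Of 8 genes of the thin limb and medulla, among them Upk1b and Cryab, 6 rose (7 adjusted over the list alone; camera adjusted p = 4.7e-05, adjusted p = 0.0764 with an estimated correlation). Markers of parts of the kidney other than the cortical tubule thus moved with this comparison.

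**Figure D4:**
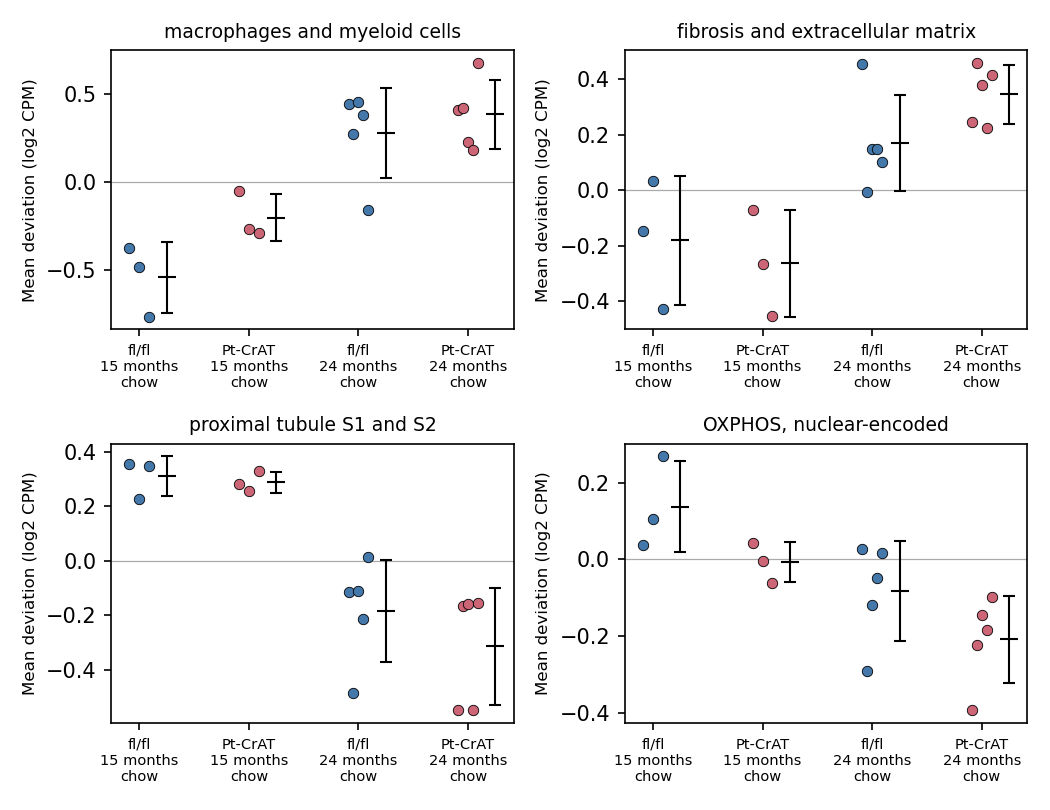
Mean deviation of log2 CPM from the average of all libraries over the genes of each list (vertical axis) in the chow libraries, by genotype and age; points are libraries, and the bars give the mean and SD of the group. Macrophage and fibrosis genes lie higher, and proximal tubule and oxidative phosphorylation genes lower, at 24 than at 15 months in both labelled genotypes.

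In all, 1705 genes passed in Pt-CrAT, 845 higher and 860 lower at 24 months, and 22 of the 40 lists were called. The number of genes was 393 and 421 without CrAT15Mchow204 and CrAT15Mchow185 at 15 months, 1097 without CrAT24Mchow136 at 24 months, and 417 without CrAT24Mchow123 and CrAT24Mchow136 together. The 15-month animals are those labelled Pt-CrAT.

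The age effects of the 2 labelled genotypes overlapped. Of the genes higher with age, 64 passed in both, where independent lists of these lengths share 7 (Fisher's exact test, two-sided p = 5.09e-47). Of those lower, 34 passed in both, where 4.1 are expected (p = 1.4e-23, same exact test). They include C3, Timp2, Acot1 and Mzb1 among the rises and F5 and Slc5a2 among the falls. Genes are not independent of one another, so these p-values are too small. No gene passed in opposite directions, and 190 of the 196 genes called in fl/fl had the same sign in Pt-CrAT. The larger number called in Pt-CrAT is not shown to be a difference between genotypes, since the test of that difference called 0 genes (2255 at an unadjusted p under 0.05; 15 by DESeq2 and, rounded, 1.5e2 by limma-voom).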

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

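Apart from the tests of the library pair CrAT12MLFD328 and Wt12MLFD326 and of a common genotype effect behind the 12-month calls, whose bounds were written before their results were seen, the tests in this part were chosen after the results they bear on; the pair itself, the scores per library and the fold changes given without pairs were picked after the libraries had been seen.

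The first pattern is the 2464 genes called between the genotypes at 12 months, which became 53 without CrAT12MLFD328, 391 without CrAT12MLFD337 and 408 without Wt12MLFD326, the library with the lowest sample quality weight (0.187). Without CrAT12MLFD328 and Wt12MLFD326 together 19 genes were called, against a median of 662 (range 49 to 4170) over the 8 other pairs of 1 library per genotype; but 49 is the value without CrAT12MLFD337 and Wt12MLFD326, so this is consistent with a difference that Wt12MLFD326 carries with either of these, and does not tell a fault of preparation from animals that differ. The median log2 fold change of the 2464 genes in their own direction went from 0.776 (median SE 0.211) to 0.485 (0.226) without the first pair and 0.534 (0.231) without the second. In the 4 pairs that join CrAT12MLFD328 or CrAT12MLFD337 to another fl/fl library it stayed at 0.759 to 0.821 with a higher SE (0.251 to 0.26). Without CrAT12MLFD345 it was 0.74 (0.223) with Wt12MLFD326 also left out, 1.01 (0.253) with Wt12MLFD327 and 0.99 (0.246) with Wt12MLFD368. These last fits called 1548, 3786 and 4170 genes, so a higher SE alone does not go with fewer calls. Why the counts changed was not tested. GC content as the whole cause is argued against by 2163 genes called after its correction, of which 1737 are among the 2464. A genotype effect common to the settings, of the size seen at 12 months, is argued against by the 24-month libraries. Their genotype difference did not enter the choice of genes. The mean score per library of the 2464 genes, in the 12-month direction, had a genotype effect of -0.165 (SE 0.127) there. It was 0.868 (SE 0.164) at 12 and 0.231 (0.164) at 15 months. Of the called genes, 21.1% had the same sign at 24 months and 82.3% at 15 months. Regroupings of the 24-month libraries gave 7.63% to 92.3%, so the share alone decides little. The value at 12 months is raised by the choice of genes, which also favours a difference among settings. The following values therefore add no weight. The score at 24 minus 12 months was -1.03 (SE 0.207, t test p at most 6.75e-04 with 1 library left out). Of the 2464 genes, 649 passed the test of a difference among settings, whose count fell from 764 to 2 without CrAT12MLFD328 and Wt12MLFD326. A smaller common effect stays open.

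The second pattern is the higher level of adipocyte markers in Pt-CrAT at 12 months, in the list fixed beforehand and in further markers chosen later (median log2 fold change 0.944). Adipose tissue in the dissected piece may account for it. Within the fl/fl libraries at 15 and 24 months, where genotype plays no part, 15 adipocyte genes moved together. Their mean pairwise correlation of deviations was 0.43 over 8 libraries, and 0 of 1000 random gene sets were as high. Markers of the same cell type are chosen to move together, so random genes are a weak comparison. The correlation shows that adipocyte transcripts varied without genotype, but does not tell where they came from. In fl/fl, 9 of the 15 are above 1 CPM. Fabp4, abundant in fat and in endothelium, does not follow, with 12.4, 20.8 and 64.4 CPM in Pt-CrAT and 66.6, 36.9 and 25 CPM in fl/fl libraries at 12 months. A genotype effect common to the 3 settings, of the size seen at 12 months, is argued against by the median of -1.39 at 24 months and by the list's mean score per library, whose genotype effect was 2.26 (SE 0.643) at 12, 0.721 (0.643) at 15 and -0.796 (0.498) at 24 months (24 minus 12 months -3.06, SE 0.813; p at most 0.00762 with 1 library left out), while a smaller one stays open. A genotype effect limited to the 12-month setting cannot be separated from dissection, since no label describes the latter.

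The third pattern is Crat at 15 months, higher in the libraries labelled Pt-CrAT. Had the labels of this setting been exchanged, genotype effects at 15 and 24 months could run against each other over genes, and their Spearman correlation was -0.345, but 12 of 100 regroupings gave one as far from 0 (others -0.573 to 0.471), so exchanged labels cannot be told apart from chance here; against an exchange, 82.3% of the 2464 genes called at 12 months had the same sign at 15 months under the labels as given, but their score did not lie beyond its spread (0.231, SE 0.164, p = 0.176). Tags outside the deleted part, which would leave Crat blind to the genotype, are argued against by its log2 fold change of -1.04 at 24 months (exact permutation p = 0.00794, 5 of 5 Pt-CrAT libraries below all fl/fl; -1.18 to -0.85 with 1 library left out), though a lower level there for another reason was not tested. No biological explanation was tested.

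Other splits of the libraries were refitted for each count. At 12 months the real split called 2464 genes and the highest other split 47, but the 10 splits of 3 against 3 are too few for a share under 0.05. Where the real count is 0, every split has as many by construction, so the splits tell nothing at 15 months (10 of 10, highest other 0), at 24 months (100 of 100, highest other 3) and for the change in the genotype difference from 15 to 24 months (100 of 100, highest other 0). For the mean of the settings, 2 of 100 splits called as many as the real 4 (highest other 11), and for the variation among settings 1 of 100 called as many as 764 (highest other 248), so few groupings of the libraries reach these counts.
The change with age in Pt-CrAT (1705 genes; highest other of 56 splits 581) was matched by 1 split, the real one, and that in fl/fl (196 genes) by 2 of 56. In fl/fl another split called 892 genes, several times the real count. What that split separates was not tested.

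Values of 1 library far from the rest of its group of 5 at 24 months were sought in 298 values, and 26 passed Dixon's limit; chance alone marks about 1 in 20 groups. The numbers are the gap to the nearest library over the range of the group. In fl/fl they were Per1 (0.89, Wt24Mchow154), Foxs1 (0.73) and Calb1 (0.923, both Wt24Mchow165), Acot1 (0.716), Ighg2c (0.869), Ighg2b (0.739) and Slc51a (0.799, all Wt24Mchow164) and Adam11 (0.711, Wt24Mchow168). In Pt-CrAT, CrAT24Mchow136 stood apart in Per1 (0.757), Spp1 (0.776), Hspa1b (0.92), Crat (0.893), Slc45a3 (0.834), Foxs1 (0.749), Per2 (0.763), Acss1 (0.754), Gsdmc2 (0.796), Gsdmc3 (0.839) and Psca (0.874). CrAT24Mchow123 stood apart in Angptl4 (0.768), Prrc2c (0.778), Timp2 (0.72) and Nccrp1 (0.773). Further ones were Fcer1g (0.899, CrAT24Mchow146) and CrAT24Mchow135 in Ces1g (0.894) and total counts (0.805).

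The genotype difference varied among the 3 settings in 764 genes, and in 46 of 122 genes named or eligible to be named for genotype. Their adjusted p-values were 0.0143 for Timm13 and Uap1l1, 0.0189 for Smim1, and 0.02 for Hp, Acads, Ndufb7, Ndufs8, Ggt1, Klf2, Brpf1, Prrc2c, Cep290, Gmppb, Afg3l1 and Acot8. They were 0.0221 for Cpxm2, 0.0251 for Hspa1b, 0.0268 for Bckdha and Cavin3, 0.0273 for Adamts15, 0.0298 for Etfb, 0.0307 for Gpatch2, 0.031 for Per1, 0.0316 for Cfd, 0.0319 for Crat, 0.0321 for Adipoq, 0.0323 for Spp1, 0.0324 for Retn and Tjp1, 0.0326 for Myoc, 0.0347 for Cidec and 0.0349 for Uqcrc1. The remaining ones were 0.0356 for Ankrd11, 0.0378 for Fasn, 0.038 for Acaa2, 0.0387 for Igfbp2, 0.0398 for Meg3, 0.04 for Lrp2, 0.0401 for Slc7a8, 0.0403 for Mmp3 and Stc1, 0.0432 for Car3, 0.0438 for Krt15 and Tubb2a, and 0.0484 for Nup88 and Dpy19l1. The directions at 15 months are those of the labels.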

How the results depend on the processing

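Leaving out 2 libraries together, the GC correction and thinning of the deepest library were chosen after the data were seen; the other alternatives were listed beforehand. Among 262 results for genes named or eligible to be named, 4364 of 5153 values under an alternative kept their side of the threshold, 685 lost and 104 gained a call, and none with a call changed sign; DESeq2 size factors kept 261 of the 262. Among 63 called lists, 742 of 922 values stayed called, 179 did not and 1 changed sign. Fry kept 34, the stricter filter 61 and DESeq2 size factors all 63, but 0 held in camera with an estimated correlation. The scaling moved the median log2 fold change of all genes by -0.0123 to 0.00659. The share of higher calls moved little (51.4 against 51.3% for genotype at 12 months, 63.3 against 59.7% for age in fl/fl). Thinning the deepest library to the median depth gave 2609 calls at 12 months in place of 2464; depth was not varied otherwise. In simulation with independent genes, 18% of 1.5-fold changes were recovered at 15 months and 40% at 24 months.

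Genes called for genotype at 12 months numbered 2464, with 3855 in limma-voom and 19 without CrAT12MLFD328 and Wt12MLFD326 together. With only the groups compared there was 1, in a fit with fewer samples whose spread comes from this setting alone. They ranged from 53 (without CrAT12MLFD328) to 3513 with 1 library left out, with 391 without CrAT12MLFD337 and 408 without Wt12MLFD326. At 15 months edgeR called 0 (1249 at an unadjusted p under 0.05; DESeq2 0), with 1 in limma-voom, 4 with only the groups compared, and 0 to 0 with 1 library left out. At 24 months it called 0 (1409 at an unadjusted p under 0.05), with 6 in DESeq2 (15728 of 16556 adjusted p-values missing), 3 in limma-voom, and 0 to 2 with 1 library left out (2 without CrAT24Mchow124, 1 each without CrAT24Mchow146 and Wt24Mchow154). For the mean of the settings, 4 genes became 9 with the stricter filter (fewer genes tested), 178 in DESeq2 and 1881 in limma-voom. They became 1 with the GC correction, 2 without CrAT12MLFD328 and Wt12MLFD326, 1 without CrAT24Mchow123 and CrAT24Mchow136, and 1 to 262 with 1 library left out (262 without Wt24Mchow154). The 764 genes that varied among settings became 2332 in DESeq2, 3120 in limma-voom, 2 without CrAT12MLFD328 and Wt12MLFD326, and 30 without CrAT24Mchow123 and CrAT24Mchow136. They became 2 (without CrAT12MLFD337) to 2195 (without CrAT12MLFD345) with 1 library left out, where 17 of 22 libraries moved it by over 1.5 times. The change in the genotype difference from 15 to 24 months had 0 in edgeR (2255 at an unadjusted p under 0.05), 15 in DESeq2, 1.5e2 (rounded) in limma-voom, and 0 to 0 with 1 library left out. Age in fl/fl had 196, 731 in DESeq2, 2024 in limma-voom, and 3 (without Wt15Mchow227) to 756 (without Wt24Mchow145). Age in Pt-CrAT had 1705, 2812 in limma-voom, 417 without CrAT24Mchow123 and CrAT24Mchow136, and 393 (without CrAT15Mchow204) to 1777. Crat kept its direction and its side of the threshold with 1 library left out, at -0.55 to -0.11 at 12 months, 0.43 to 0.87 at 15, -1.18 to -0.85 at 24, and -0.33 to -0.17 for the mean.

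Lists called were 1 at 12 months (0 with an estimated correlation; 0 to 1 with 1 library left out, 0 without CrAT12MLFD345), and 3 at 15 months (0 with an estimated correlation, 0 in fry; 2 to 6, with 5 without CrAT15Mchow185 and 6 without Wt15Mchow205). They were 13 at 24 months (0, 0 in fry, 8 without CrAT24Mchow123 and CrAT24Mchow136; 7 to 19, with 8 without CrAT24Mchow123 and 7 without Wt24Mchow145) and 7 for the mean (0, 1 in fry, 13 without CrAT12MLFD328 and Wt12MLFD326; 4 to 12, with 4 without CrAT12MLFD345, 11 without CrAT24Mchow124 or Wt24Mchow164 and 12 without CrAT24Mchow135 or Wt12MLFD326). They were 17 for age in fl/fl (0 with an estimated correlation; 14 to 20) and 22 for age in Pt-CrAT (0 with an estimated correlation; 19 to 24). The proximal tubule S3 list at 24 months reversed without CrAT24Mchow123 and CrAT24Mchow136 (adjusted p = 0.872). The cause of these changes was not tested.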

Other observations

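The genes and libraries in this part were picked after their values were seen. Single libraries picked this way were not tested as a group, and at 15 months none of these genes passed between the labelled genotypes (adjusted p = 0.581 for Upk3a, Krt15 and Sprr1a).

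CrAT24Mchow123 and CrAT24Mchow136 at 24 months had low levels of genes that the male kidney expresses under androgen control. Kap stood at 4570 and 2850 CPM, against 18900 to 28800 CPM in the other 3 Pt-CrAT and 24300 to 32400 CPM in the 5 fl/fl libraries of that age. The organic anion transporter Slco1a1 stood at 3.47 and 1.06 CPM against 24.1 to 122 CPM in the other 8, and the S3 transporter Slc7a13 at 157 and 133 CPM against 275 to 490 CPM. The fatty acid hydroxylase Cyp4a14 was at 1620 and 2340 CPM in these libraries and at 58.2 to 672 CPM in the others. The Y-linked transcripts Ddx3y (65.7 to 89.5 CPM) and Uty (19.6 to 38.1 CPM) were present in all 22 libraries. S100a8 was at 56 and 47 CPM in the 2 libraries, but also at 51.7 and 65 CPM in Wt24Mchow164 and Wt24Mchow165.

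Transcripts of the urothelium that lines the renal pelvis were low in the libraries labelled Pt-CrAT at 15 months. Upk3a stood at 1.2, 0.212 and 0.402 CPM there, against 3.98 to 5.02 CPM in those labelled fl/fl and 2.75 to 13.7 CPM in the 10 libraries at 24 months. Krt15 followed with 0.527, 0.142 and 0.0804 CPM against 1.61 to 2.34 CPM at the same age, and Sprr1a with 0.563 to 1.27 CPM against 3.69 to 5.15 CPM. CrAT12MLFD328 at 12 months was low in the same transcripts, with 0.639 CPM of Upk3a, 0.0913 CPM of Krt15 and 1 CPM of Sprr1a, where the other 5 libraries of that setting held 5.18 to 9.28 CPM of Upk3a. From 15 to 24 months the 3 transcripts rose in Pt-CrAT.

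The clock gene Per1 was lower in fl/fl at 24 months (8.72 to 9.99 CPM in 4 of 5 libraries, but 20.3 CPM in Wt24Mchow154) than in the 11 other chow libraries (20.2 to 44.4 CPM), and stood at 8.22 to 14.4 CPM in all 6 libraries at 12 months. The hour of sampling is not given in the sources used here.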
